A study of Rattus norvegicus with 20 samples.

How the data were processed

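The series measured microRNAs (miRNAs, short RNAs that repress target messages) in male germ cells of rats given cyclophosphamide or saline, on 20 one-colour Agilent arrays labelled with Cy3. Per the labels' protocols, Sprague-Dawley males received the drug by gavage at 6 mg/kg, or saline in its place, on 6 days a week for 4 weeks. Pachytene spermatocytes and round spermatids were then separated by sedimentation at unit gravity, RNA was extracted with TRIzol and RNeasy, and 100 ng of total RNA was labelled. The labels put the arrays into 4 groups of 5 and give each array a number, which is taken here as that of its rat. The same numbers recur in both treatments and both cell types. If the numbers mark rats, equal numbers in different treatments are different rats, since a rat received either the drug or saline. The labels do not settle whether an equal number in the 2 cell types of a treatment means the same rat. The replicates within a group carry different numbers, apart from 2 cyclophosphamide pachytene rats numbered 16 that a year in the labels tells apart, so the p-values measure the spread between rats as far as those numbers mark separate animals.

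The deposited scanner files hold spot intensity values on a linear scale, background-subtracted but not scaled between arrays, made with Agilent Feature Extraction 11.5.1.1 per the submitters' processing notes and the file headers. Each file lists 14255 spots, of which 13540 carry probes for 677 rat miRNAs and 715 are controls. The file of the cyclophosphamide round spermatid array of rat 14 holds its processed signal rounded to 3 significant digits, and it was used as it stands. The deposited value table of the whole series holds log2 values made by the authors, with every miRNA centred on a median of 0 over the arrays and with column medians between -0.12 and 0.40, by a normalization not given in the sources used here. Its scale was read from the values. It was used as an alternative only, for the 44 tested miRNAs that matched by name and correlated at r over 0.5 with the scanner values (median r 0.888 over the 49 tested miRNAs matched by name). Per array, over those 49 miRNAs, the median r was 0.537 and the lowest 0.437.

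The main values were the processed signals divided by each array's 75th percentile over the 2176 spots that were well above background on all arrays, then brought back to a common level, held at a floor of 12.17 (3.61 on the log2 scale) and taken to log2. Control spots and spots marked as outliers were left out, between 379 and 635 outlier spots per array, and no spot was saturated. The spots of a probe were averaged. Of the probes of a miRNA, the one with the brightest mean over all arrays stood for it. The arrays carry 2 probes for 514 miRNAs, 4 for 133, 3 for 27 and 1 for 3. A miRNA was tested if Feature Extraction detected it on all arrays of at least 1 group, which left 217 miRNAs for testing and 460 untested. Names are those of the array design. Between 18.9% and 31.4% of spots per array were well above background, and the number of arrays limits the precision of every value. No genome coordinates are given, since the gene table used here belongs to another assembly than the array design.

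Groups were compared with limma 3.58.1 in R 4.3.3, in 1 model with a mean for each of the 4 groups and 16 residual degrees of freedom. The 5 comparisons were cyclophosphamide against saline in each cell type, the difference of these effects, and round spermatids against pachytene spermatocytes in each treatment. Adjusted p-values follow Benjamini and Hochberg over the 217 miRNAs, with a threshold of 0.05. The 19 miRNA lists comprise families, genomic clusters, the p53 and DNA damage response and markers of other cell types. The 15 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Camera compares a list with all other miRNAs. Fry asks whether a list's members move on balance in one direction and, in its mixed form, whether they move in either direction, and neither form compares them with other miRNAs. The lists overlap: 18 of their 114 distinct tested members stand in more than 1 list, among them all 7 of the miR-34 and miR-449 family. Array-wide measures were compared with exact two-sided permutation tests over all 252 splits of 5 arrays against 5. Figures were drawn with Python 3.11.15.

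Bounds are given where Feature Extraction detected a miRNA on no array of a group. Where it was detected on some arrays, the fitted value is given and depends on the floor. For a bound, the fold is the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the miRNA's own signal. It is written as at least that fold.

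The miRNAs named in the text follow a rule fixed, like the groups, lists, tests and the first set of alternatives below, before the data were examined. For the treatment comparisons and their difference it takes all miRNAs past the threshold, at most the 20 with the largest change, and where fewer than 10 pass, the 10 with the smallest p. For the cell types it takes the 12 most increased and the 12 most decreased in saline rats, with their values in cyclophosphamide rats. From each list it takes up to 4 members with the smallest p in that comparison.

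The analysis was tested on simulated data with the real arrays' means and spread, 217 miRNAs, 20 changed per fold and 20 simulations per comparison. The first version of that test failed its own check, so its simulation and its measure were revised, and its limit of 20% for false calls was set after its results had been seen. It is therefore no independent evidence of the error rate. Changes of 2-fold were called in 94.75% of cases for the treatment in pachytene spermatocytes, 92.75% for the treatment in round spermatids, 80.5% for the difference of effects and 94.25% and 96% for the cell types in saline and cyclophosphamide rats. Changes of 1.5-fold were called in 77.75%, 74.75%, 49.5%, 73% and 73% in the same order. Unchanged miRNAs made up 4.30%, 17.2%, 8.29%, 12.7% and 15.6% of the calls in the same order, above the nominal 5% in 4 of the 5 comparisons. The spread was larger in round spermatids than in pachytene spermatocytes (median SD 0.251 against 0.163 in saline rats), which a shared variance does not follow.

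The alternatives were normexp background correction with an offset of 50, no filter on dim miRNAs, only miRNAs detected on all 20 arrays, the floor at 0.5 of its value, the percentile over all spots, no scaling, quantile normalization, the total gene signal of Feature Extraction, the mean over all probes, the deposited value table, the slide and the scan date as a block, each slide alone, the rat number as a block, fits of only the groups compared, array weights, a trended and robust variance model, and leaving out each array in turn. Normexp was intended for mean spot signals, which were not used here, and was run on median spot signals instead. Added after the data had been seen were that form of normexp, normexp with quantile normalization, scaling to the labelling spike-ins, the arrays without slide 3, no scaling with the slide as a block, and the main values of the miRNAs matched in the deposited table. The 20 arrays lie on 3 slides, and no other sample's columns were used.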

Results

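The series profiled miRNAs in 2 stages of rat male germ cells after long exposure to cyclophosphamide, an alkylating drug used against cancer and as an immunosuppressant. Pachytene spermatocytes are cells in the long prophase of meiosis, and round spermatids are the haploid cells that follow meiosis. There were 20 arrays, 5 each of saline pachytene spermatocytes, cyclophosphamide pachytene spermatocytes, saline round spermatids and cyclophosphamide round spermatids. Each array has a number in its label, which is taken as that of its rat. In cyclophosphamide pachytene spermatocytes 2 rats carry the number 16 and differ by a year in the labels, and they are called the earlier and the later rat 16. Of 677 rat miRNAs on the array, at most 281 were detected on an array. The means were 235.2 ± 29.6 (SD, n = 5) in saline and 232.8 ± 13.8 in cyclophosphamide pachytene spermatocytes, and 216.6 ± 21.4 and 213.6 ± 22.6 in round spermatids. The 217 miRNAs detected on all arrays of at least 1 group were tested, and the number of arrays limits the precision of each value. Replicate arrays of a group correlated at r between 0.958 and 0.996 over 40 pairs. The array name prefix for rat is left out of the miRNA names below.

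The miR-34b, miR-34c and miR-449a precursors, known from meiotic and later male germ cells, had 5p arms detected on all 5 arrays of each group. The log2 signal in saline rats was 12.87 ± 0.26 (SD, n = 5) for miR-34b-5p, 12.46 ± 0.27 for miR-449a-5p and 12.29 ± 0.30 for miR-34c-5p in pachytene spermatocytes, and 13.50 ± 0.46, 12.20 ± 0.42 and 12.76 ± 0.43 in round spermatids. The first principal component held 70.2% of the variance and parted the cell types, with pachytene arrays between -7.13 and -4.42 and spermatid arrays between 3.62 and 6.53. The second held 9.50%, and the 4 arrays of slide 3, all of round spermatids, lay at its upper end. Among the 10 spermatid arrays, 18 miRNAs differed between slide 3 and the others with treatment in the model, 3 higher and 15 lower, among them miR-487b-3p at -1.35 and miR-212-3p at -1.13 on the log2 scale.

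**Figure D1:**
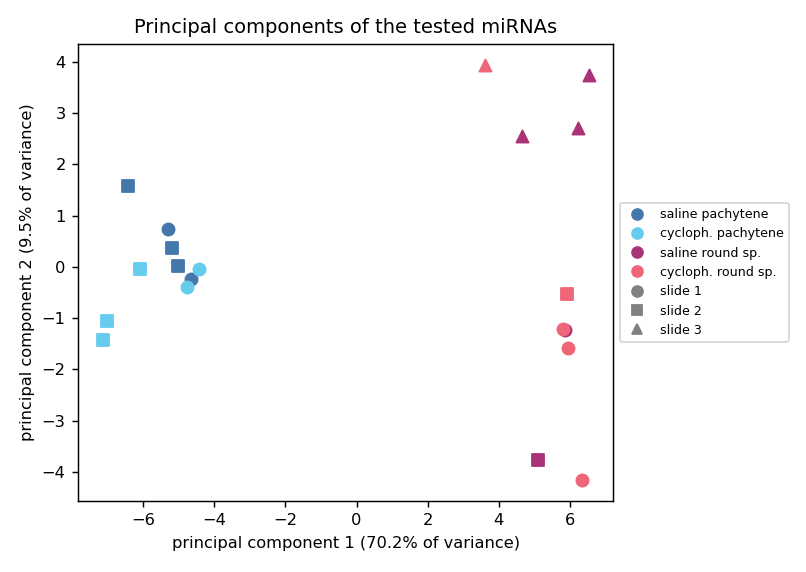
Scores of the 20 arrays on the first 2 principal components of the log2 signals of the 217 tested miRNAs, coloured by group and with a marker per slide. The first component (70.2% of variance) separates pachytene spermatocytes from round spermatids, while the treatments overlap.

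The first comparison asked which miRNAs of pachytene spermatocytes differ after chronic cyclophosphamide. None passed the test. The smallest p belonged to miR-351-3p, an X-linked miRNA, with a log2 signal of 4.26 ± 0.25 (SD, n = 5) in saline and 4.57 ± 0.20 in cyclophosphamide rats. The log2 difference was 0.32 ± 0.10 (SE), with an adjusted p of 1 by limma. miR-494-3p of the imprinted Dlk1-Dio3 cluster had the largest difference, 0.39 ± 0.25, and miR-7a-5p stood at -0.35 ± 0.21. The values were -0.31 ± 0.20 for miR-126a-5p, typical of endothelium, -0.26 ± 0.18 for miR-497-5p of the miR-15 and miR-16 family, 0.25 ± 0.16 for miR-328a-3p, 0.21 ± 0.14 for miR-3562, 0.19 ± 0.10 for miR-181b-5p, 0.16 ± 0.10 for miR-877 and 0.12 ± 0.07 for miR-99b-3p. Of the 217 miRNAs, limma called 0, and 1 had an unadjusted p under 0.05 where chance gives 10.85. With array weights it called 0 as well, with 27 at an unadjusted p under 0.05, and in a fit of these 2 groups alone 0, with 17. The 95% interval of the difference lay within 2-fold in either direction for all but 2 miRNAs. A fit with the slide as a block called 0, as did slide 1 and slide 2 alone, with 2, 2 and 22 at an unadjusted p under 0.05. There miR-351-3p stood at 0.32, 0.41 and 0.25, in that order.

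In the germ cell lists, no member was called in pachytene spermatocytes, over all tested miRNAs or adjusted over the list alone (0 higher and 0 lower in each list). The median log2 difference was 0.01 for the 7 tested members of the miR-34 and miR-449 family and 0.05 for the 6 testis-enriched germ cell miRNAs, all of which the former list also holds. It was 0.04 for the 23 members of the X-linked spermatogenesis cluster, the region of the miR-506 family, and 0.01 for 16 other X-linked miRNAs. Families known for roles in proliferation and differentiation lay near 0, at -0.03 for the 11 members of miR-17~92 and miR-106b~25, -0.04 for 9 of let-7, -0.05 for 6 of miR-15, miR-16, miR-195 and miR-497, -0.01 for 3 of miR-29 and 0.0034 for 9 of miR-30. The 14 members of the p53 and DNA damage response list, chosen because the drug's products crosslink DNA, had a median of -0.0010, with 0.38 ± 0.33 (SE) for miR-34c-3p and -0.30 ± 0.23 for miR-143-3p. The 6 members of the Dlk1-Dio3 cluster had a median of 0.19, with 0.31 ± 0.23 for miR-770-3p. Marker lists of other cells stood at 0 for 5 spermatogonial, 0.02 for 3 Sertoli cell, -0.11 for 10 endothelial, muscle and mesenchymal and -0.11 for 4 blood cell miRNAs. Camera called 0 of the 15 lists, with 5 at an unadjusted p under 0.05. The adjusted p lay between 0.0715 and 0.833, and between 0.322 and 0.868 as adjusted p with an estimated correlation. Its direction was down for the p53, miR-30, spermatogonial and Sertoli cell lists, whose mean was above 0. Within slide 2 it called the X-linked cluster (median 0.10, adjusted p = 0.00180) and miR-17~92 (-0.13, 0.000608). Scaled to the total gene signal it called miR-17~92 and let-7 (both 0.0376) and miR-15 and miR-16 (0.0422), and with no filter on dim miRNAs the X-linked cluster (0.0209). Under normexp, chosen after the data were seen, it called miR-17~92 (0.00166), let-7 (0.00289), p53 (0.000531), miR-29 (0.0142), and miR-34 and miR-449 (0.00842) and the testis-enriched list (0.0354), whose medians turned to -0.15 and -0.08. Lists too small for a test gave -0.04 for miR-141-3p, the 1 tested member of the miR-200 family, 0.17 for miR-290, the 1 of the miR-290 and miR-302 clusters, and 0.19 and -0.0047 for miR-181b-5p and miR-181a-5p, the 2 of the miR-181 family. The miR-183, miR-96 and miR-182 cluster had 0 tested members. Leaving out 1 array gave a camera call to 5 lists. These were the X-linked cluster without cyclophosphamide rat 7 (adjusted p = 0.0243), cyclophosphamide rat 15 (0.0282) or saline rat 26 (0.0376), and miR-17~92 without cyclophosphamide rat 7 (0.00213) or rat 15 (0.0306). Further ones were let-7 without the later cyclophosphamide rat 16 (0.0236) or rat 29 (0.00478), miR-15 and miR-16 without cyclophosphamide rat 15 (0.0347) or saline rat 26 (0.0376), and the mesenchymal list without cyclophosphamide rat 15 (0.0448) or saline rat 13 (0.0223).

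The same question was asked of round spermatids, and none passed there either. miR-34c-3p, the less abundant arm of the miR-34c precursor, had the smallest p. The log2 signal was 6.31 ± 0.78 (SD, n = 5) in saline and 7.20 ± 0.23 in cyclophosphamide rats. The difference was 0.89 ± 0.33 (SE), or 1.85-fold, with a 95% interval from 0.19 to 1.59 and an adjusted p of 0.848 by limma. It was 0.92 with the slide as a block, 1.89 within slide 1, -0.07 within slide 2 and 0.92 within slide 3, and 0.32 as the mean over all probes of the miRNA. Differences of 0.26 ± 0.20 for miR-34c-5p, 0.23 ± 0.19 for miR-34b-5p and 0.23 ± 0.19 for miR-449a-5p went the same way without passing. miR-134-5p and miR-487b-3p, both of the Dlk1-Dio3 cluster, stood at 0.33 ± 0.14 and 0.57 ± 0.30, and at 0.14 and 0.03 with the slide as a block. The values were 0.41 ± 0.17 for miR-141-3p of the miR-200 family, -0.34 ± 0.15 for miR-1949, 0.21 ± 0.10 for miR-667-3p, -0.26 ± 0.12 for miR-365-3p and -0.39 ± 0.19 for miR-146a-5p, a target of NF-kappa B signalling. They were 0.21 ± 0.10 for the X-linked miR-742-3p and 0.19 ± 0.10 for miR-187-3p. Limma called 0 of 217, with 5 at an unadjusted p under 0.05, and with array weights 0, with 29. The interval lay within 2-fold for 211 miRNAs. These intervals use a spread shared by all 4 groups and may be too narrow here. The median SD was 0.251 in saline and 0.230 in cyclophosphamide round spermatids, against 0.163 and 0.166 in pachytene spermatocytes. With the slide as a block 0 were called, with 9 at an unadjusted p under 0.05, within slide 1 0 with 3 and within slide 3 0 with 24. Within slide 2 27 were called, 14 higher and 13 lower. A single array stood for saline on slide 1, for cyclophosphamide on slide 3 and for both on slide 2, and was assumed to vary like the other groups, so that 1 array can set these values and those of the lists by slide.

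**Figure D2:**
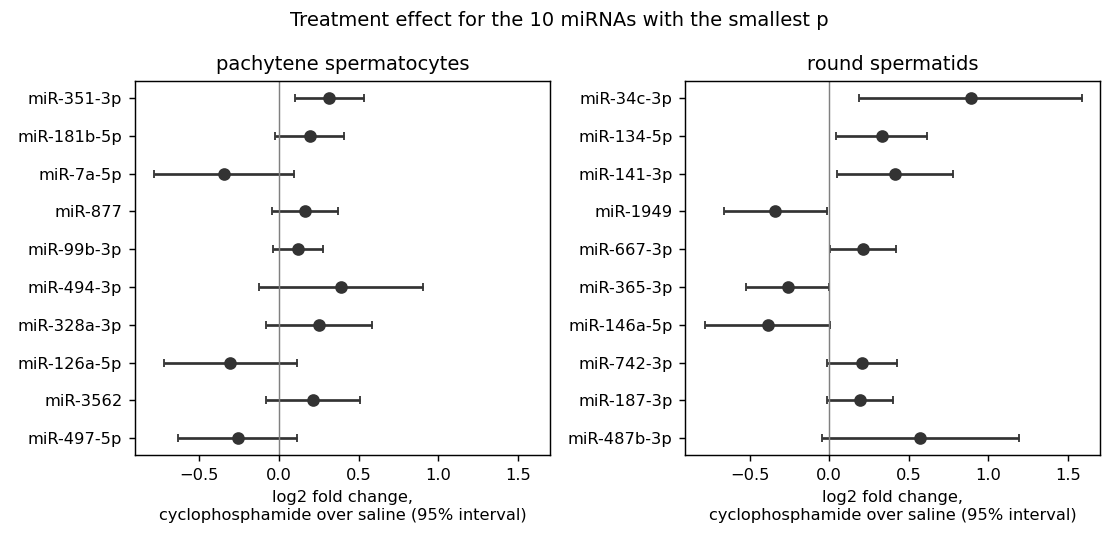
Log2 fold change of cyclophosphamide over saline, with 95% intervals, for the 10 miRNAs with the smallest p in pachytene spermatocytes (left) and in round spermatids (right), 5 arrays per group. None passed an adjusted p of 0.05, and the largest difference was 0.89 for miR-34c-3p in round spermatids. The intervals use 1 spread shared by all 4 groups, though the spread was larger in round spermatids.

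Again no list member was called in round spermatids, over all tested miRNAs or adjusted over the list alone (0 higher and 0 lower in each list). Camera called 2 lists as wholes, let-7 with a median log2 difference of -0.10 and the imprinted Dlk1-Dio3 cluster with 0.31, both at an adjusted p of 0.00974 and both at an adjusted p = 0.446 with an estimated correlation, which ended the calls. In the let-7 family, let-7b-5p stood at -0.13 ± 0.12 (SE) and let-7i-5p at -0.12 ± 0.09, and in the Dlk1-Dio3 cluster miR-770-3p stood at 0.35 ± 0.23 beside miR-134-5p and miR-487b-3p. Blocked by slide, the medians were -0.04 (adjusted p = 0.265) for let-7 and 0.04 (0.608) for Dlk1-Dio3. Within slides 1, 2 and 3 they were 0.05, -0.07 and -0.25 for let-7, and 0.22, -0.33 and 0.16 for Dlk1-Dio3, in neither case with 1 direction on every slide, though each slide had at least 1 treatment with a single array. Scaled to the labelling spike-ins let-7 stood at 0.12, where the median over all miRNAs was 0.18. Over all alternatives the adjusted p ran from 0.00128 to 0.985 for let-7 and from 0.000158 to 0.985 for Dlk1-Dio3. The let-7 call was lost without cyclophosphamide rat 15 (adjusted p = 0.117), saline rat 17 (0.0578) or saline rat 25 (0.318), and the Dlk1-Dio3 call without cyclophosphamide rat 14 (0.0640), saline rat 17 (0.0584) or saline rat 28 (0.0610). The let-7 call was also lost without scaling (0.0636), and the Dlk1-Dio3 call with no filter on dim miRNAs (0.629). With the scan date as a block both were lost (0.242 and 0.518), as under normexp (0.827 and 0.174). The let-7 call was lost with the spike-ins (0.258), and both calls without slide 3 (both 0.985). The other medians were 0.23 for the miR-34 and miR-449 family, 0.23 for the testis-enriched miRNAs, 0.04 for the X-linked cluster, 0.00064 for other X-linked miRNAs (mean -0.0029), 0.10 for miR-17~92, 0.06 for the p53 list, 0.04 for miR-29, 0.02 for miR-30 and -0.03 for miR-15 and miR-16. Marker lists of other cells stood at 0.24 for Sertoli cells, -0.06 for endothelial, muscle and mesenchymal cells, -0.10 for blood cells and 0.02 for spermatogonia, where the mean was -0.06 and the direction of the test down. Camera's adjusted p for these 13 lists lay between 0.114 and 0.946. Blocked by slide it was 0.0279 for the miR-34 and miR-449 family (median 0.24) and 0.0243 for the X-linked cluster (median 0.10). Within slide 3 it was 0.00776 for the X-linked cluster (median 0.21) and 0.00138 for the mesenchymal list (median -0.62), both resting on cyclophosphamide rat 26 alone, and within slide 2 0.0155 for miR-29 (median 0.37). Among settings chosen after the data were seen, both the miR-34 and miR-449 family and the testis-enriched list were called with the labelling spike-ins (0.0467) and with normexp (3.59e-06), and without scaling but with the slide as a block (0.00287 and 0.00617). Normexp also called miR-17~92 (0.0386), p53 (0.000204) and miR-29 (0.0490). With quantile normalization the medians of the miR-34 and miR-449 family and the testis-enriched list were 0.0030 and 0.02 (both 0.408). That normalization gives miR-34b-5p, the brightest tested miRNA on every array, 1 value by construction, so these medians cannot show a change of it. Without 1 array camera called the Sertoli cell list (0.0304 without cyclophosphamide rat 26, 0.027 without saline rat 16) and the mesenchymal list (0.0430 without cyclophosphamide rat 25). The values were 0.10 ± 0.10 for miR-181b-5p, -0.12 ± 0.14 for miR-181a-5p and 0.16 ± 0.21 for miR-290.

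The difference between the drug's effect in round spermatids and in pachytene spermatocytes was tested directly, and no miRNA passed. miR-351-3p had the smallest p, with -0.31 ± 0.15 (SE) and an adjusted p of 0.998 by limma, and its effect in pachytene spermatocytes met a spermatid signal at the floor. miR-487b-3p had the largest difference, 0.65 ± 0.42, which was 0.11 with the slide as a block. Further values were 0.45 ± 0.25 for miR-141-3p, 0.44 ± 0.30 for miR-7a-5p, -0.42 ± 0.30 for miR-32-3p, -0.41 ± 0.26 for miR-466b-2-3p, -0.39 ± 0.27 for miR-146a-5p, -0.26 ± 0.18 for miR-10a-5p, 0.22 ± 0.14 for miR-667-3p and 0.15 ± 0.10 for miR-30e-5p. Limma called 0 of 217, with 1 at an unadjusted p under 0.05, and with array weights 0, with 5. The interval lay within 2-fold for 200 miRNAs. Scaled to the labelling spike-ins, the median over all miRNAs moved to -0.26 in pachytene spermatocytes, 0.18 in round spermatids and 0.46 for the difference, and without scaling to -0.13 in pachytene spermatocytes, so treatment values under these scalings are read relative to it. With the slide as a block 0 were called, with 2 at an unadjusted p under 0.05, within slide 1 0 with 2, and within slide 2, with 1 spermatid array per treatment, 20.

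No list passed for the difference, and no member was called over all tested miRNAs or adjusted over the list alone (0 higher and 0 lower in each list). miR-17~92 and miR-106b~25, clusters that promote proliferation, came closest, with a median of 0.13 and a camera adjusted p of 0.0507 (adjusted p = 0.806 with an estimated correlation). Among its members miR-25-3p stood at 0.22 ± 0.18 and miR-93-5p at 0.20 ± 0.17. It was 0.15 with the slide as a block (adjusted p = 0.0208), -0.22 within slide 1 (0.00256) and 0.36 within slide 2 (0.0165), with a single saline spermatid array on slide 1 and 1 spermatid array per treatment on slide 2, so that 1 array can set either sign. It was also called with quantile normalization (0.0395), the total gene signal (0.00340), only miRNAs detected on all arrays (0.0123), a lower floor (0.0340) and the scan date as a block (0.0128). Among settings chosen after the data were seen, it was called with the spike-ins (0.0187), without scaling but with the slide as a block (0.0182) and with normexp and quantile normalization (0.0466). Normexp alone called it too (0.00136), with miR-34 and miR-449 (6.57e-05), testis-enriched (0.000231), p53 (4.51e-05) and miR-29 (0.00953). The miR-29 family was called within slide 2 as well (0.40, 0.0165). For miR-17~92 over all alternatives the adjusted p ran from 0.000628 to 0.657. Without 1 array it was called without cyclophosphamide pachytene rat 7 (0.000628) or 15 (0.00897), saline pachytene rat 13 (0.0233) or 28 (0.0119), cyclophosphamide spermatid rat 14 (0.0140), 16 (0.0424) or 25 (0.0210), and saline spermatid rat 15 (0.0242), 17 (0.0301) or 28 (0.00791). The medians were 0.22 for the Sertoli cell list (0.0919), -0.10 for other X-linked miRNAs (0.153), 0.10 for Dlk1-Dio3 (0.228), 0.23 for miR-34 and miR-449 and 0.24 for testis-enriched miRNAs (both 0.372; both medians 0 with quantile normalization), 0.09 for the p53 list (0.369), and -0.04 for let-7 (0.372). They were 0.05 for miR-29, 0.00026 for miR-30, 0.09 for miR-15 and miR-16, 0.00015 for the X-linked cluster, -0.06 for spermatogonia, -0.01 for mesenchymal (mean 0.02) and -0.02 for blood cells. The last 7 had an adjusted p of at least 0.723. Quantile normalization gives miR-34b-5p, the brightest tested miRNA on every array, 1 value by construction, so the medians of 0 there cannot show a change of it. Dropping saline spermatid rat 16 called Dlk1-Dio3 and the Sertoli cell list (both 0.00334). Dropping cyclophosphamide spermatid rat 26 called the Sertoli cell list (0.0397), and dropping saline pachytene rat 25 called miR-34 and miR-449 and the testis-enriched list (both 0.0451).

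The design also sets round spermatids against pachytene spermatocytes within each treatment. In saline rats the largest increase was that of miR-7a-5p, abundant in neuroendocrine cells, from 5.20 ± 0.48 (SD, n = 5) in pachytene spermatocytes to 8.17 ± 0.30 in round spermatids on the log2 scale. It rose by 2.97 ± 0.21 (SE), or 7.83-fold, with an adjusted p of 2.07e-09 by limma. In cyclophosphamide rats it rose by 3.41, or 10.6-fold. The myeloid miR-223-3p rose by 2.15 ± 0.15 (4.43-fold), from 3.96 ± 0.31 to 6.11 ± 0.21, and by 1.95 in cyclophosphamide rats. miR-146a-5p rose by 2.01 ± 0.19 and by 1.62, from a pachytene signal at the floor, where it was detected on 3 and on 2 of 5 arrays. Of the 12 largest increases, 5 belonged to the list of endothelial, muscle and mesenchymal miRNAs, namely miR-145-5p (1.88 ± 0.32 in saline, 1.76 in cyclophosphamide rats) and miR-143-3p (1.81 ± 0.23 and 2.0), a pair from 1 cluster known from smooth muscle. The others were both arms of the mesenchymal miR-199a (1.84 ± 0.27 and 1.84 for the 3p arm, 1.58 ± 0.29 and 1.73 for the 5p arm) and the muscle miRNA miR-133b-3p (1.57 ± 0.15 and 1.48). Another pair from 1 cluster, miR-497-5p and miR-195-5p, rose by 1.70 ± 0.18 and 1.52 ± 0.15, with 1.89 and 1.61 in cyclophosphamide rats. Further increases were those of miR-10b-5p of a Hox cluster by 1.56 ± 0.16 and miR-23a-3p by 1.47 ± 0.19, with 1.53 and 1.46 in cyclophosphamide rats.

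Among the decreases, miR-34a-5p, a transcriptional target of p53, led with a log2 change of -1.96 ± 0.19 (SE) in saline rats. It went from 10.32 ± 0.18 (SD, n = 5) in pachytene spermatocytes to 8.37 ± 0.32 in round spermatids, a 3.88-fold decrease with an adjusted p of 1.17e-07 by limma. In cyclophosphamide rats it stood at -1.90. X-linked miRNAs made up 6 of the 12 largest decreases. From the spermatogenesis cluster, miR-201-5p stood at -1.88 ± 0.24 (-2.08 in cyclophosphamide rats), miR-547-3p at -1.73 ± 0.17 (-1.80) and miR-201-3p at -1.64 ± 0.16 (-1.64). From elsewhere on the X, miR-221-3p stood at -1.64 ± 0.21 (-1.70), its cluster partner miR-222-3p at -1.40 ± 0.14 (-1.55) and miR-652-3p at -1.14 ± 0.12 (-1.32). The gonadal miR-202-3p stood at -1.77 ± 0.18 (-1.55), miR-138-5p at -1.64 ± 0.12 (-1.69), and miR-3585-5p at -1.60 ± 0.21 (-1.87). Next came miR-338-3p at -1.51 ± 0.24 (-1.30) and miR-129-2-3p at -1.48 ± 0.15 (-1.44). In round spermatids, miR-201-3p was detected on 2 of 5 saline arrays, miR-138-5p on 2 of 5 and miR-222-3p on 1 of 5, so their decreases rest on values near the floor.

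**Figure D3:**
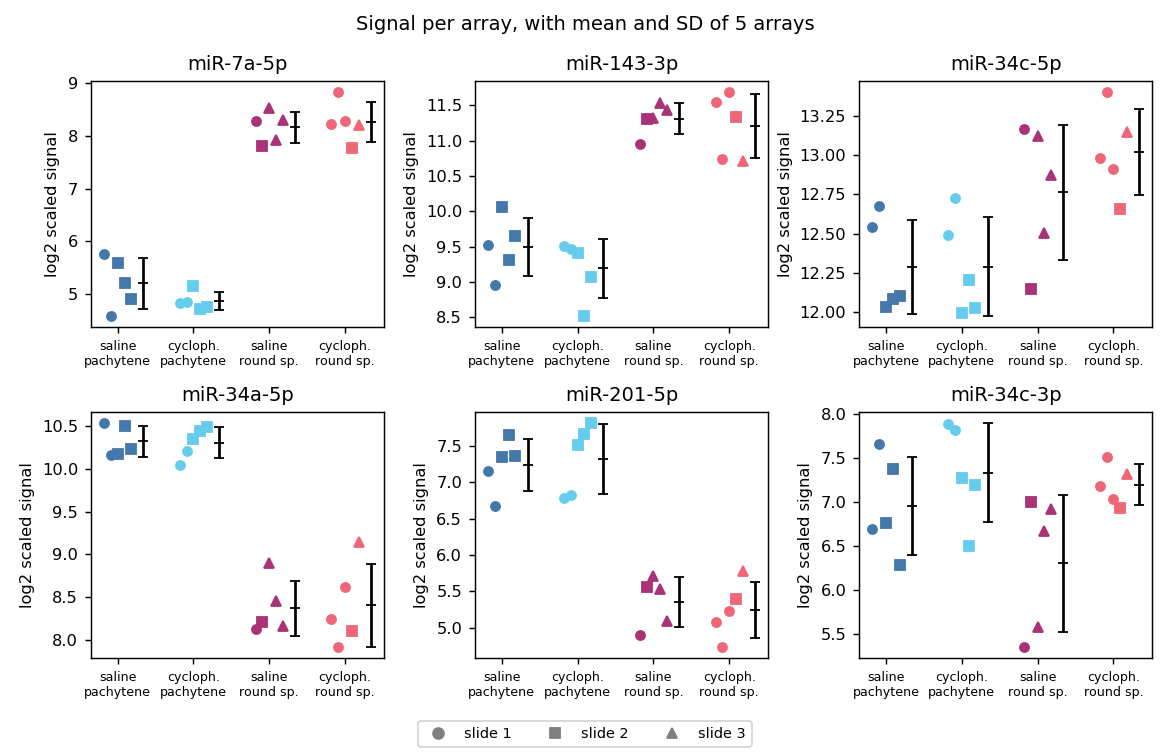
Log2 scaled signal per array in the 4 groups, with the mean and SD of 5 arrays and a marker per slide, for miR-7a-5p, miR-143-3p, miR-34c-5p, miR-34a-5p, miR-201-5p and miR-34c-3p. The signal of miR-7a-5p lay at 5.20 ± 0.48 in saline pachytene spermatocytes and at 8.17 ± 0.30 in saline round spermatids, and miR-34a-5p at 10.32 ± 0.18 and 8.37 ± 0.32.

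In all, 105 of 217 miRNAs passed in saline rats, 57 higher and 48 lower in round spermatids, and 117 passed in cyclophosphamide rats, 67 higher and 50 lower. Of these, 96 passed in both, all in the same direction, and the changes correlated at r = 0.98 across miRNAs, which are not independent replicates. Over 2-fold were 39 in saline (23 higher, 16 lower) and 38 in cyclophosphamide rats (21 and 17). For all 24 of the named increases and decreases, no array of one cell type overlapped the other, in either treatment. The same held for 75 of the 217 miRNAs in saline and 92 in cyclophosphamide rats, where chance gives 0.794% or 1.72. With the slide as a block 108 passed in saline (57 higher, 51 lower) and 74 higher and 52 lower in cyclophosphamide rats, within slide 1 56 and 73, and within slide 2 125 and 114. The saline spermatid arm within slide 1 and both spermatid arms within slide 2 were a single array each, assumed to vary like the other groups, here and for the lists. In saline rats, by block, slide 1 and slide 2, miR-7a-5p stood at 2.88, 3.12 and 2.58 and miR-34a-5p at -2.29, -2.23 and -2.10. In simulated data with 20 miRNAs changed per fold, unchanged miRNAs made up 12.7% of the calls for saline and 15.6% for cyclophosphamide rats. The counts may thus carry an uncertainty beyond the 5% that the adjustment allows. Its size here is not known, since far more miRNAs were called than were changed in the simulation.

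The balance of higher and lower calls depended on the scaling. The median over all tested miRNAs was 0.02 in saline rats with the main scaling, -0.15 with the percentile over all spots, -0.37 without scaling, -0.05 with quantile normalization, -0.09 with the total gene signal and -0.98 when scaled to the labelling spike-ins. The calls there were 36 higher and 78 lower, 21 and 68, 45 and 63, 46 and 59, and 4 and 157, in that order. They were 48 and 66 for normexp with quantile normalization and 13 and 53 without scaling and with the slide as a block. In cyclophosphamide rats the median was 0.06 with the main scaling, -0.07, -0.23, -0.01, -0.04 and -0.46 in the same order. The calls were 39 higher and 72 lower, 22 and 50, 50 and 60, 56 and 53, and 19 and 87. They were 54 and 65 for normexp with quantile normalization and 20 and 48 without scaling and with the slide as a block. All 24 leading miRNAs kept their direction under these 6 scalings, also relative to the median of all miRNAs, with 2.76 to 3.11 for miR-7a-5p and -2.16 to -1.93 for miR-34a-5p in saline rats relative to it. Values near the floor ranged more widely, from -3.34 to -1.04 for miR-222-3p, -3.22 to -1.27 for miR-138-5p, -2.79 to -1.27 for miR-201-3p and 1.98 to 3.51 for miR-146a-5p. For miR-133b-3p the range was 1.54 to 2.35. Smaller changes named below depended more on the scaling. With quantile normalization the calls of miR-34b-5p, miR-19b-3p, let-7b-3p, miR-30e-3p, miR-15b-5p and miR-16-5p were lost in saline rats (adjusted p by limma of up to 1), and in cyclophosphamide rats those of miR-34b-5p, miR-34c-5p, miR-19b-3p, miR-98-5p, miR-30e-3p, miR-30c-2-3p, miR-16-5p and miR-487b-3p (up to 1). With the percentile over all spots 10 such calls were lost in saline rats, those of miR-34b-5p, miR-19b-3p, let-7b-3p, miR-29a-3p, miR-29c-3p, miR-30e-3p, miR-15b-5p, miR-16-5p, miR-770-3p and miR-132-3p (up to 0.802). In cyclophosphamide rats they were those of miR-34c-5p, miR-25-3p, miR-19b-3p, miR-29b-3p, miR-29c-3p, miR-30e-3p, miR-30c-2-3p, miR-16-5p, miR-770-3p, miR-487b-3p and miR-142-3p (up to 0.612). Scaled to the labelling spike-ins, 4 of the 12 increases still passed in saline rats. Under normexp alone, 3 of the 24 changed direction in saline rats.

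**Figure D4:**
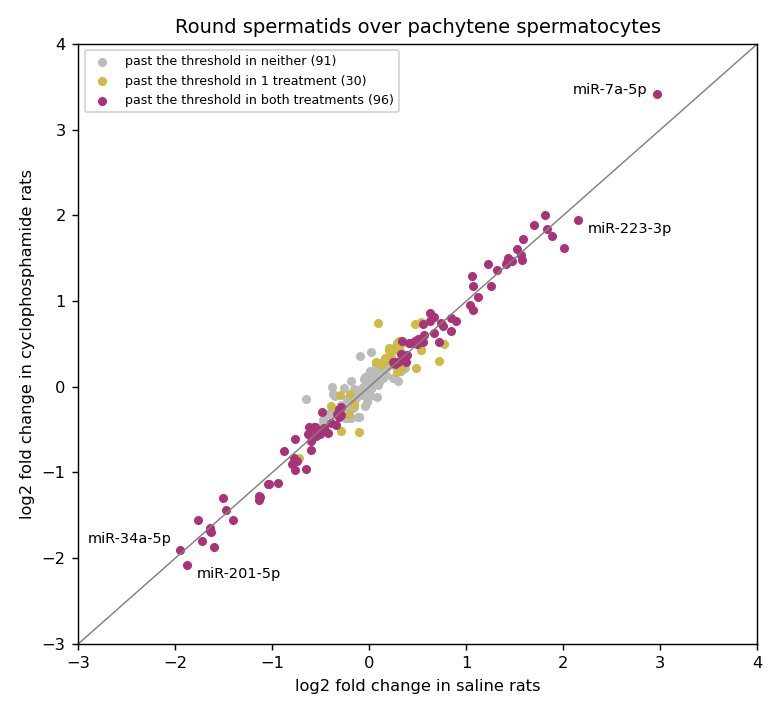
Log2 fold change of round spermatids over pachytene spermatocytes for the 217 tested miRNAs, in saline rats (x axis) and cyclophosphamide rats (y axis), coloured by which comparison passed an adjusted p of 0.05. The changes correlated at r = 0.98 across miRNAs, and 96 passed in both.

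The X-linked spermatogenesis cluster, whose miRNAs are abundant in the testis, was lower in round spermatids. Of its 23 tested members, 13 fell, 2 rose and 8 were not called in saline rats, with the same counts in cyclophosphamide rats and when adjusted over the list alone. Beside the leading members, miR-547-5p stood at -0.49 and -0.51, and the members that rose were miR-742-5p and miR-883-5p, both at 0.27 in saline rats. The list's median was -0.33 in saline and -0.33 in cyclophosphamide rats, with camera adjusted p of 0.000364 and 0.000562. These were adjusted p = 0.632 and 0.605 with an estimated correlation, which ended both calls. Fry, which asks only whether members move on balance one way, gave an adjusted p of 4.4e-05 in saline rats. With the slide as a block the median was -0.34 (adjusted p = 6.37e-05) and -0.29 (0.000335), within slide 1 -0.20 (0.0196) and -0.25 (0.0161), and within slide 2 -0.44 and -0.56. Relative to all miRNAs it lay between -0.35 and -0.45 under 5 scalings in saline rats, and over all alternatives camera's adjusted p ran from 2.43e-09 to 0.0196. Of 16 other X-linked miRNAs, 3 rose and 6 fell in saline rats and 3 and 7 in cyclophosphamide rats, likewise adjusted over the list alone, with medians of -0.20 and -0.20 (camera adjusted p of 0.505 and 0.383). They included miR-223-3p upward and miR-221-3p, miR-222-3p and miR-652-3p downward. miR-351-3p was detected on no round spermatid array, and its signal there was at least 1.33-fold lower in saline and at least 1.56-fold lower in cyclophosphamide rats.

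The marker list of endothelial, muscle and mesenchymal cells, which make up the wall of the tubule and the tissue around it, was higher in round spermatids. Of 10 tested members, 8 rose, 0 fell and 2 were not called in saline rats, and 8 rose and 1 fell in cyclophosphamide rats, each 8 and 1 when adjusted over the list alone. The medians were 1.21 (camera adjusted p of 0.0398) and 1.14 (0.0585, not called), with adjusted p = 0.632 and 0.605 with an estimated correlation, so that no call held. The endothelial miR-126a-3p went the other way, at -0.73 (adjusted p = 0.0583 by limma) in saline and -0.83 (0.0294) in cyclophosphamide rats. Blocked by slide, the medians were 1.42 (adjusted p = 0.103) and 1.21 (0.0660), within slide 1 1.13 (0.0712) and 1.32, and within slide 2 1.21 (0.0324) and 1.22 (0.00392). Over all alternatives the adjusted p ran from 9.31e-05 to 0.103 in saline and from 0.000460 to 0.140 in cyclophosphamide rats. The saline call was lost without saline pachytene rat 13 (0.0722) or 16 (0.0623) or saline spermatid rat 16 (0.0547) or 25 (0.0887). A call was gained in cyclophosphamide rats without the earlier cyclophosphamide pachytene rat 16 (0.0465), cyclophosphamide spermatid rat 15 (0.0226) or 26 (0.0284), or saline spermatid rat 17 (0.0464). The saline call was also lost with the mean over all probes (0.0623), only miRNAs detected on all arrays (0.0852), the scan date as a block (0.0993) and normexp (0.0899). The cyclophosphamide call was gained with the percentile over all spots (0.00869), no scaling (0.00274), quantile normalization (0.0291), no filter on dim miRNAs (0.00831) and a lower floor (0.0478). It was also gained, in settings chosen after the data were seen, with the spike-ins (0.000460), without slide 3 (0.0198) and without scaling but with the slide as a block (0.00180). Of 5 spermatogonial miRNAs, 1 rose (miR-146a-5p) and 3 fell (miR-221-3p, miR-222-3p and miR-21-5p at -0.20) in saline rats, and 1 and 2 in cyclophosphamide rats (medians -0.20 and -0.09, camera adjusted p of 0.505 and 0.602). Of 3 Sertoli cell miRNAs, miR-132-3p rose by 0.33, miR-202-3p fell and miR-212-3p stood at 0.02 in saline rats, with 1 up and 1 down in cyclophosphamide rats too, and with medians of 0.02 and 0.41 against means of -0.47 and -0.21. The test ran downward, with adjusted p of 0.725 and 0.978. The saline pachytene signal of miR-132-3p lay at the floor, detected on 1 of 5 arrays, and its value ran from 0.12 to 2.47 over 6 scalings. Of 4 blood cell miRNAs, miR-223-3p rose in saline rats and miR-142-3p joined it in cyclophosphamide rats at 0.76 (0.53 in saline rats, adjusted p = 0.0565 by limma), with 0 lower. In saline rats miR-142-3p was called without saline pachytene rat 13, 16 or 26 or saline spermatid rat 16 (adjusted p between 0.0234 and 0.0460). The medians were 0.14 and 0.20 against means of 0.49 and 0.49, with camera adjusted p of 0.530 and 0.602. Fry, which does not compare a list with other miRNAs, called it upward (adjusted p of 9.98e-05 and 9.44e-05). These 3 lists gave the same counts adjusted over the list alone.

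**Figure D5:**
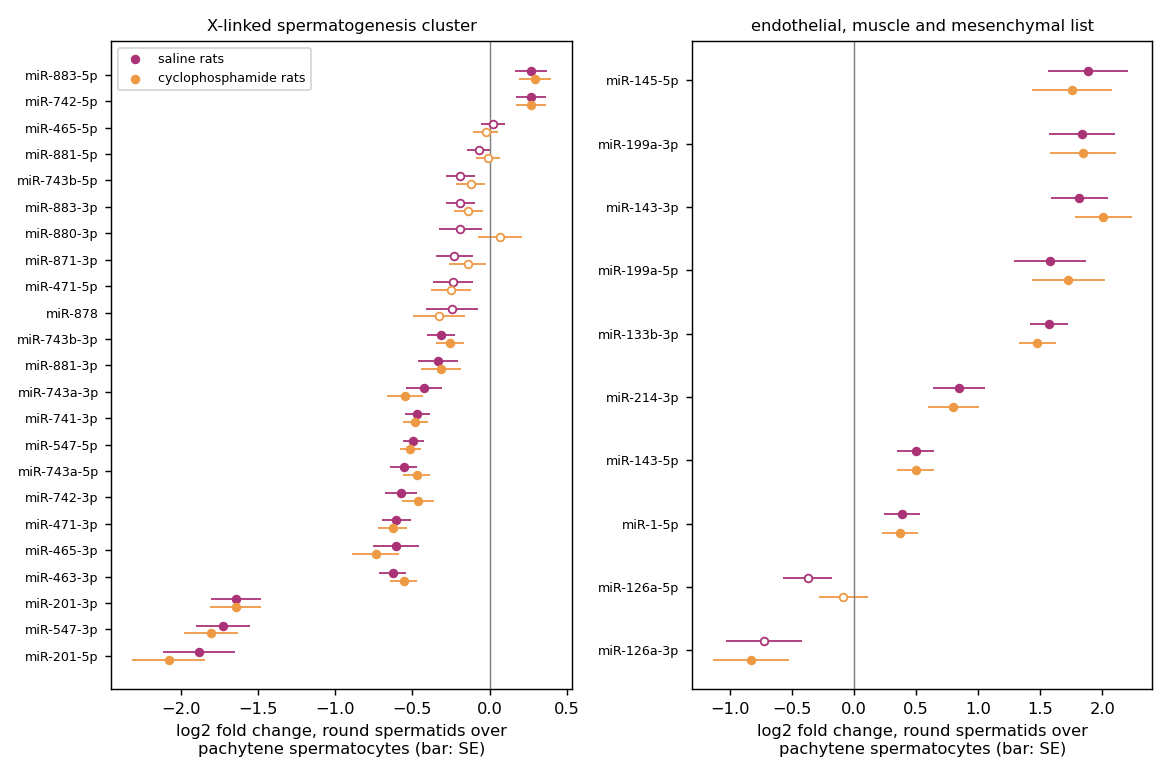
Log2 fold change of round spermatids over pachytene spermatocytes, with SE bars, for each tested member of the X-linked spermatogenesis cluster (left) and of the list of endothelial, muscle and mesenchymal miRNAs (right), in saline and cyclophosphamide rats, with filled points past an adjusted p of 0.05. Of the 23 cluster members 13 were lower and 2 higher, and of the 10 list members 8 were higher in saline rats.

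The p53 and DNA damage response list and the families that overlap it moved unevenly between the cell types. Of the 14 p53 members, 6 rose and 2 fell in saline rats (7 and 2 adjusted over the list alone) and 8 and 2 in cyclophosphamide rats, with medians of 0.33 and 0.46 (camera adjusted p of 0.505 and 0.439). Their 11 members shared with other lists include the mesenchymal miR-143-3p and miR-145-5p among those that rose, while miR-34a-5p and miR-107-3p (-0.79 in saline rats) fell. In the miR-34 and miR-449 family of 7, miR-34b-5p rose by 0.63 ± 0.19 (adjusted p = 0.00990 by limma) and miR-34a-5p and miR-449a-3p fell in saline rats. In cyclophosphamide rats miR-34b-5p (0.86) and miR-34c-5p (0.73) rose and the same pair fell, likewise adjusted over the list alone (medians -0.26 and -0.01, camera adjusted p of 0.505 and 0.602). In saline rats miR-34c-5p was at 0.47 (adjusted p = 0.0584 by limma) and miR-34c-3p at -0.65 ± 0.33. The former was called without cyclophosphamide pachytene rat 15, saline pachytene rat 13 or 16, or saline spermatid rat 16 or 25 (adjusted p between 0.00967 and 0.0496). With quantile normalization miR-34b-5p stood at 0 in both treatments (adjusted p of 1 by limma) and miR-34c-5p at 0.19 in both (0.0623 and 0.0617), so that no call of either held. As the brightest tested miRNA on every array, miR-34b-5p is given 1 value there by construction, so its lost call decides nothing on its rise. Whether the rank of miR-34c-5p, also among the bright miRNAs, limits its value in the same way was not tested. Scaled to the spike-ins, miR-34b-5p and miR-34c-5p turned to -0.56 and -0.72 in saline rats, against a median of all miRNAs of -0.98. miR-449a-3p was detected on no round spermatid array, at least 1.73-fold lower in saline and at least 1.75-fold lower in cyclophosphamide rats. The testis-enriched list of 6 holds members of that family only, with 1 up and 1 down in saline and 2 and 1 in cyclophosphamide rats (medians -0.04 and 0.06, the second with a downward test, adjusted p of 0.757 and 0.995). In the miR-15, miR-16, miR-195 and miR-497 family of 6, 4 rose and 0 fell in both treatments (4 and 1 in cyclophosphamide rats adjusted over the list alone), among them miR-15b-5p (0.62) and miR-16-5p (0.41) beside miR-195-5p and miR-497-5p. The medians were 0.52 and 0.64, with camera adjusted p of 0.178 and 0.251 and a fry adjusted p of 6.26e-07 in saline rats, and the median was -0.51 in saline rats scaled to the spike-ins, where all miRNAs stood at -0.98. Relative to all miRNAs it lay between 0.22 and 0.51 over the scalings. Camera called it in saline rats with no filter on dim miRNAs (0.0277) and in cyclophosphamide rats under normexp (0.0281).

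Among the other families, the called members of miR-29 rose and both of miR-181 fell, while the rest held calls in both directions or none in saline rats. In miR-17~92 and miR-106b~25, miR-17-5p (-0.88 ± 0.11), miR-106b-5p (-0.77 ± 0.11), miR-20a-5p (-0.40) and miR-93-5p (-0.30) fell and miR-19b-3p (0.42) rose in saline rats. Thus 1 of 11 rose and 4 fell (1 and 3 adjusted over the list alone), against 3 and 2 in cyclophosphamide rats (medians -0.14 and -0.10, camera adjusted p of 0.505 and 0.602). The miR-19b-3p call was lost without saline pachytene rat 25 (adjusted p = 0.0612 by limma) or saline spermatid rat 15 (0.0505). Of 9 let-7 members, let-7b-5p (-0.51) and let-7c-5p (-0.32) fell and let-7b-3p (0.53) rose in saline rats, and 0 rose and 3 fell in cyclophosphamide rats (medians -0.0018 and -0.06, adjusted p of 0.757 and 0.602). Of these saline calls, let-7b-3p was lost without saline pachytene rat 25, 26 or 28 or saline spermatid rat 16, 25 or 28 (adjusted p between 0.0514 and 0.0680), and let-7c-5p without saline pachytene rat 13, 25 or 26 or saline spermatid rat 15, 17 or 28 (between 0.0558 and 0.0998). Of 3 miR-29 members, miR-29a-3p (0.51) and miR-29c-3p (0.37) rose in saline rats and all 3 in cyclophosphamide rats (adjusted p of 0.432 and 0.383), and the median of 0.37 in saline rats was -0.82 when scaled to the spike-ins, where all miRNAs stood at -0.98. Relative to all miRNAs it lay between 0.10 and 0.42 over the scalings. Of 9 miR-30 members, miR-30a-5p (-0.40) fell and miR-30e-3p (0.29) rose in saline rats, with 2 and 2 in cyclophosphamide rats, where the median of 0.02 met a downward test (adjusted p of 0.725 and 0.868). These 3 families gave the same counts adjusted over the list alone. In the Dlk1-Dio3 cluster of 6, miR-134-5p (-0.62) fell and miR-770-3p (0.57) rose in saline rats (0 up and 1 down adjusted over the list alone) and 3 rose and 1 fell in cyclophosphamide rats (medians 0.22 and 0.41, adjusted p of 0.790 and 0.602). The miR-770-3p call in saline rats was lost without any one of 13 of the 20 arrays, with an adjusted p of up to 0.143, the highest without saline spermatid rat 16. Both tested members of the miR-181 family fell, miR-181a-5p by 0.74 and miR-181b-5p to at least 1.09-fold lower in saline rats, and miR-141-3p (-0.10 and 0.35) and miR-290 (-0.26 and -0.27) were not called. Camera's adjusted p with an estimated correlation lay between 0.632 and 0.888 over the 15 lists in saline and between 0.605 and 0.997 in cyclophosphamide rats, so that no call of a list held with it.

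Array-wide measures were compared in a family of 20 exact two-sided permutation tests, none past an adjusted p of 0.05, where the smallest p that 5 arrays against 5 can give is 0.00794. The labelling spike-in dmr_31a, an added control RNA, was brighter on saline spermatid arrays (343 ± 97.9, SD, n = 5) than on saline pachytene arrays (187 ± 26.3; exact p = 0.00794, adjusted p = 0.159), and the labelling spike-in dmr_285 gave 937 ± 275 against 571 ± 73.9 (exact p = 0.0159, adjusted p = 0.159). The hybridisation spike-in dmr_3 lay between 13925 and 15513 on slide 3 and between 2805 and 6928 elsewhere.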

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

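The tests on whether slides explain the mesenchymal list, on slides and scaling for the X-linked cluster, and both spike-in tests were chosen only after the result was seen, and the prediction for the labelling reaction was rewritten after its own value was known; the counts over other splits, the test for RNA of other cells and the test on values at the floor were written before. Within groups, 168 sets of 5 arrays were examined over 45 of the miRNAs named above and the array-wide measures, and in 10 of them 1 array stood apart from the other 4 by more than 0.71 of the whole range. Chance flags about 1 in 20 groups, or 8.4 of these. In saline pachytene spermatocytes, rat 16 stood apart for miR-134-5p (0.753 of the range; log2 signal 6.29 against 5.88 to 5.98) and for miR-338-3p (0.772; 4.74 against 5.60 to 5.85). In cyclophosphamide pachytene spermatocytes, rat 15 stood apart for miR-99b-3p (0.806; 3.61 against 3.81 to 3.86) and miR-126a-5p (0.958; 4.00 against 3.61 to 3.62), the later rat 16 for miR-497-5p (0.727; 5.25 against 5.62 to 5.76) and rat 29 for the labelling spike-in dmr_31a (0.869; 153 against 231 to 243). In saline round spermatids, rat 16 stood apart for miR-494-3p (0.725; 11.08 against 9.59 in the lowest array) and miR-667-3p (0.893; 3.94 against 3.61 to 3.64), and rat 17 for miR-338-3p (0.766; 4.72 against 3.67 to 3.92). In cyclophosphamide round spermatids, rat 26, the treatment's array on slide 3, stood apart for miR-199a-3p (0.761; 5.27 against 6.47 to 6.85).

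Other splits of the same arrays into groups of the same sizes were fitted, 100 per comparison with the real one included. For the drug in pachytene spermatocytes, in round spermatids and for the difference of effects, the real split called 0 in each with limma, with 1, 5 and 1 at an unadjusted p under 0.05. A count of 0 is matched by all 100 splits whatever the data, so the splits decide nothing on chance there. The highest count of another split was 13, 51 and 33, and 7, 28 and 12 of the 99 other splits called any. Such counts could come from a structure of the samples other than treatment, or from a test that calls too much in round spermatids, where unchanged miRNAs made up 17.2% of the calls in simulated data, and the 2 were not told apart. The pachytene split with 13 calls put all 4 arrays of slide 1 together with saline rat 25, and a spermatid split with 42 calls put all 4 arrays of slide 3 on the same side. The splits with 51 and 33 calls did not, with 3 and with 2 of these 4 arrays on one side, so slide 3 alone would not account for them. For round spermatids against pachytene spermatocytes, only 1 of 100 splits, the real one, called as many in saline rats (105, highest other 52). The same held in cyclophosphamide rats (117, highest other 60). A share of 1 in 100 is the smallest these splits can give, so chance is argued against but not excluded. Every other split put both cell types into each group, which adds their difference to the spread within groups. The real split also holds a slide difference, since slide 3 carries only spermatid arrays.

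The first pattern weighed is the rise of the endothelial, muscle and mesenchymal list in round spermatids, which sedimentation at unit gravity separates by size and not by markers. A slide difference is argued against, since the median rise was 1.42 in saline rats with the slide as a block and 1.32 within slide 1 in cyclophosphamide rats, with 3 spermatid arrays, while the saline values of 1.13 within slide 1 and 1.21 within slide 2 rest on 1 spermatid array each. RNA of other cells in the spermatid fractions remains a candidate explanation: with group and slide removed, the 8 called members had a mean pairwise r of 0.442 over the 10 spermatid arrays, the 99.71 percentile of 10000 random sets (median 0.031). Of these, 7 had a mean r with the others between 0.52 and 0.59 and miR-1-5p one of -0.35. The members hold both arms of miR-143 and both of miR-199a, and miR-145 shares a cluster with miR-143, which could also make them vary together. The random sets were drawn without regard to shared precursors or clusters, so the percentile does not tell these 2 explanations apart. The log2 signal of miR-143-3p was 11.31 in saline round spermatids, 3 tested members stand in the p53 list too, and markers of other cells went both ways in saline rats, with miR-126a-3p at -0.73 (adjusted p = 0.0583 by limma) and miR-202-3p at -1.77 but miR-223-3p at 2.15 and miR-142-3p at 0.53 (adjusted p = 0.0565), so that purity stays open, as does a true change between meiotic and haploid cells, which was not tested.

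The second pattern is the lower X-linked spermatogenesis cluster in round spermatids. Slides as the whole cause are argued against by medians of -0.34 in saline and -0.29 in cyclophosphamide rats with the slide as a block and -0.25 within slide 1 in cyclophosphamide rats, while the saline values of -0.20 within slide 1, close to the bound of -0.2 set for the test, and -0.44 within slide 2 rest on 1 spermatid array each. The list lay between -0.35 and -0.45 relative to all miRNAs under 5 scalings. Scaling by 1 factor per array cancels in this measure except near the floor. Only quantile normalization, at -0.35, could have differed, so scaling is argued against only as far as that setting tests it. Values held at the floor are argued against as the whole cause, since the 17 members detected on all arrays had a median of -0.31, with 9 lower and 2 higher. Lower levels in round spermatids than in pachytene spermatocytes remain a hypothesis, found and tested on the same arrays. The call of the list as a whole by camera did not hold with an estimated correlation (adjusted p = 0.632).

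The third pattern is a lower miRNA signal in round spermatids relative to the labelling spike-ins. The total miRNA signal per array, not scaled to any spike-in, did not pass a test. It was 59022 ± 18018 (SD, n = 5) in saline round spermatids and 68393 ± 22203 in saline pachytene spermatocytes (exact permutation p = 0.5). In cyclophosphamide rats it was 59922 ± 21397 against 59924 ± 7119. Scaled to them, the median over miRNAs per array was 4.73 ± 0.45 (SD, n = 5) in saline round spermatids and 5.99 ± 0.41 in saline pachytene spermatocytes (difference -1.26, exact permutation p = 0.00794, adjusted p = 0.0159), and 5.03 ± 0.43 against 5.72 ± 0.34 in cyclophosphamide rats (-0.69, exact permutation p = 0.0238, adjusted p = 0.0238). Without slide 3, whose spike-ins were brighter, the median log2 change of all miRNAs was still -0.78 in saline and -0.38 in cyclophosphamide rats, so brighter spike-ins there may account for part of it, and how much cannot be told apart with 2 saline spermatid arrays left, of which rat 15 (5.43) lay near the saline pachytene arrays of its slide (5.51 and 5.77) and rat 16 (4.49) far from those of its own (5.90 to 6.59). Scaling to the hybridisation spike-ins, added after labelling, gave -1.03 and -0.43 without slide 3, which poorer labelling of spermatid RNA would give as well. The -0.78 and -0.38 were measured against the labelling spike-ins, so a labelling difference that these spike-ins share is already scaled out there. A labelling difference that the spike-ins do not share stays open. A smaller share of miRNA in the total RNA of round spermatids stays open and was not tested.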

How the results depend on the processing

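Chosen only after the result was seen were the tests with normexp on median spot signals, alone or with quantile normalization, with scaling to the labelling spike-ins, without slide 3, without scaling but with the slide as a block, and on the main values of the miRNAs matched in the deposited table. Leaving out each array in turn gave 0 calls by limma for both treatment comparisons and the difference, 97 to 112 for the cell types in saline and 103 to 123 in cyclophosphamide rats. The 24 leading cell type miRNAs were called in all 480 such values per treatment. Over all alternatives 986 of their 1030 values in saline rats kept direction and call, 41 lost the call and 3 turned, and in cyclophosphamide rats 971 of 982 kept both and 11 lost the call. The saline counts, here and over all named miRNAs, include the fit with both rat number and slide. That fit called none and cannot part the cell types from the slides. Over all named miRNAs 11764 values kept their side of the threshold without a called turn, 368 lost a call, 101 gained one and 69 turned. For list medians these were 2656, 32, 85 and 7. Array-wide measures, of which none passed after adjustment, were counted at an unadjusted exact p of 0.05, where 236 values kept their side, 4 fell short, 5 came to pass and 0 turned. Few probes were well above background, which limits values near the floor.

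The treatment counts differed in 1 setting each: within slide 2, with 1 spermatid array per treatment, 27 in round spermatids and 20 for the difference. For the cell types, normexp gave 28 calls in saline and 38 in cyclophosphamide rats. Its median over all miRNAs was 0.41 in saline rats, and with quantile normalization added it gave 114 there. Among the 44 matched miRNAs, the deposited table gave 17 and 17 and the main values 17 and 19, fewer since fewer were tested. Slide 1 alone, with fewer arrays, gave 56 and 73. No scaling gave 72 in cyclophosphamide rats, no scaling with the slide as a block 66 and 68, and the labelling spike-ins 161 in saline rats. Beyond fewer arrays or miRNAs and shifts of the overall median under other scalings, the cause was not tested.

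Equal rat numbers were taken as a replicate block where 3 or more numbers recur. As a fixed block the number gave 63 calls in saline rats, 61 of them among the 105, and 0 with the slide added (52 at an unadjusted p under 0.05). In round spermatids the fixed block called 0 for treatment, with 10 at an unadjusted p under 0.05. A random block of equal numbers within a treatment gave 0, 0, 0, 108 and 116 over the 5 comparisons. Deviations of equal numbers between the cell types correlated at 0.07, 0.18 and -0.30 for saline rats 16, 25 and 28, and at 0.13 for cyclophosphamide rat 15. With the slide removed these were 0.51, 0.13, -0.08 and -0.27. Between the treatments in round spermatids, where equal numbers are taken as different rats, deviations correlated at 0.61, -0.0017 and 0.34 for rats 15, 16 and 25. With the slide removed these were 0.45, -0.36 and 0.14. Not every correlation was positive and not every array correlated best with its own number, so the numbers are not shown to pair the arrays. No fit with the number as a fixed block was made where fewer than 3 recur: only 16 recurs for treatment in pachytene spermatocytes and for the difference, and only 15 and 16 for the cell types in cyclophosphamide rats, where 2 pachytene rats carry 16 and the labels give no year for the spermatid rat. With the fixed block and slide, turned values in saline rats were miR-34b-5p -0.11, miR-19b-3p -0.12, let-7b-5p 0.042, let-7c-5p 0.084, miR-30e-3p -0.089, miR-181a-5p 0.27 and miR-181b-5p 0.33. That fit cannot estimate the cell type change apart from the slides, so these signs say nothing on its direction.

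Other values that turned are given by setting. Without scaling they were miR-19b-3p -0.051, miR-29c-3p -0.10, miR-30e-3p -0.18 and miR-16-5p -0.068 in saline rats, and miR-29c-3p -0.11 and miR-30e-3p -0.12 in cyclophosphamide rats. With the slide as a block as well, saline rats gave miR-34b-5p -0.20, miR-19b-3p -0.36, let-7b-3p -0.059, miR-29a-3p -0.23, miR-29c-3p -0.34, miR-30e-3p -0.48, miR-15b-5p -0.11 and miR-16-5p -0.28. There cyclophosphamide rats gave miR-25-3p -0.068, miR-19b-3p -0.073, miR-29b-3p -0.068, miR-29c-3p -0.14, miR-30e-3p -0.21 and miR-16-5p -0.051. Scaled to the labelling spike-ins, saline rats gave miR-34b-5p -0.56, miR-34c-5p -0.72, miR-19b-3p -0.77, let-7b-3p -0.043, miR-29a-3p -0.68, miR-29c-3p -0.82, miR-29b-3p -0.88, miR-30e-3p -0.90, miR-15b-5p -0.57, miR-16-5p -0.78, miR-770-3p -0.62, miR-494-3p -0.66, miR-370-3p -0.76 and miR-212-3p -1.17. Cyclophosphamide rats gave miR-25-3p -0.17, miR-19b-3p -0.17, miR-29a-3p -0.12, miR-29b-3p -0.14, miR-29c-3p -0.38, miR-30e-3p -0.39, miR-16-5p -0.16 and miR-770-3p -0.071. These 3 settings lowered the median over all miRNAs, to -0.37 and -0.98 in saline rats for the first and the last. Under normexp, saline rats gave miR-201-3p 0.0011, miR-338-3p 0.0070, miR-222-3p 0.073, miR-449a-3p 0.17, miR-547-5p 0.40, miR-181b-5p 0.38 and miR-134-5p 0.10, and cyclophosphamide rats miR-30c-2-3p -0.0014 and miR-667-3p -0.013. For treatment in pachytene spermatocytes normexp gave medians of -0.15 for the miR-34 and miR-449 family and -0.080 for the testis-enriched list. Within slide 1, let-7b-3p was at -0.13 in saline rats, the let-7 median at 0.047 for treatment in round spermatids and miR-17~92 at -0.22 for the difference. Within slide 2, treatment in round spermatids gave miR-667-3p -0.15, miR-29c-3p 0.37, miR-30c-2-3p -0.28, miR-202-3p -0.87 and a Dlk1-Dio3 median of -0.33. The difference gave miR-29c-3p 0.40, miR-30c-2-3p -0.28 and miR-202-3p -1.03 there, and saline rats miR-29c-3p -0.0013, miR-29b-3p -0.35 and miR-30e-3p -0.048. Without slide 3 the medians for treatment in round spermatids were 0.051 for let-7 and -0.0064 for Dlk1-Dio3. Slides hold fewer arrays, and for the rest the cause was not tested.

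Leaving out 1 array ended 7 calls of named miRNAs in cyclophosphamide rats. They were let-7c-5p without cyclophosphamide pachytene rat 29 (adjusted p = 0.0551 by limma) or spermatid rat 15 (0.0538), miR-29c-3p without spermatid rat 25 (0.0540), miR-667-3p without spermatid rat 14 (0.0573) or 26 (0.0505), and miR-98-5p of the let-7 list without pachytene rat 29, either pachytene rat 16, or spermatid rat 14 or 15 (0.0572 to 0.0783). The others were miR-30c-5p without pachytene rat 29, the later pachytene rat 16 or spermatid rat 14 or 26 (0.0573 to 0.0836), and miR-770-3p without pachytene rat 7, 15, 29 or the earlier rat 16 or spermatid rat 14, 15 or 25 (0.0515 to 0.0896). The miR-487b-3p call was lost without any cyclophosphamide array but spermatid rat 26, or without saline pachytene rat 25 (0.0503 to 0.107). Calls were gained there by let-7b-3p without spermatid rat 16 (0.0402) or saline spermatid rat 15 (0.0458), miR-141-3p without pachytene rat 15 or spermatid rat 16 (both 0.0401), miR-146b-5p without pachytene rat 15 (0.0287) and miR-212-3p without spermatid rat 26 (0.0350). In saline rats, calls beyond those given with the results were gained by miR-29b-3p (0.000907), miR-30c-5p (0.0267), miR-290 (0.0274) and miR-150-3p (0.0234) without saline spermatid rat 16, and by miR-494-3p without saline spermatid rat 28 (0.0398).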

Other observations

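The test of the arms of a precursor was written before its result was seen, and the miRNAs of this paragraph were chosen after their values were seen. The miR-23, miR-27 and miR-24 clusters, a pair of clusters with related members, were higher in round spermatids in all 5 tested members, miR-23a-3p included. In saline rats miR-23b-3p rose by 1.42 ± 0.16 (SE, adjusted p = 4.05e-07 by limma), miR-24-3p by 1.41 ± 0.16, miR-27b-3p by 1.32 ± 0.13 and miR-27a-3p by 1.22 ± 0.21, with 1.45, 1.43, 1.36 and 1.43 in cyclophosphamide rats. The neuronal miR-124-3p (1.43 ± 0.16 and 1.5), miR-152-3p (1.25 ± 0.17 and 1.17) and miR-218a-5p (1.12 ± 0.12 and 1.04) rose as well. Lower in round spermatids were miR-129-1-3p (-1.13 ± 0.19 and -1.28), a second copy of the miR-129 precursor, miR-100-5p (-1.04 ± 0.13 and -1.14) and miR-204-5p (-0.95 ± 0.13 and -1.12). Also lower was miR-103-3p, which shares its seed with miR-107-3p, at -0.46 ± 0.08 and -0.48. Under 6 scalings and relative to the median of all miRNAs, the 7 higher ones lay between 1.01 and 2.51 in saline rats and between 0.94 and 2.73 in cyclophosphamide rats, and the 4 lower ones between -1.34 and -0.46 and between -1.42 and -0.49. In saline rats miR-27a-3p stood at 1.29 with the slide as a block, 1.51 within slide 1 and 0.74 within slide 2, and scaled to the spike-ins at 0.03. The corresponding values of miR-124-3p by slide were 1.20, 1.36 and 0.94, and those of miR-129-1-3p -1.40, -1.71 and -0.93. Each value within a slide rests on 1 saline spermatid array.

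A precursor gives a 5p and a 3p arm, and a change in its transcription would be expected to move both. Over the 33 precursors with both arms tested, the cell type changes of the arms correlated at r = 0.506 across precursors in saline rats, the 99.84 percentile of 10000 random pairings, and at 0.505 (99.8) in cyclophosphamide rats. Spearman's rho was only 0.230 (89.7) and 0.287 (94.55) in the same order, so the relation was weaker by rank. Precursors are not independent replicates. Of 9 precursors with both arms called in saline rats 6 moved the same way and 3 opposite ways (let-7b, miR-652 and miR-742, seen after the fact), and of 8 in cyclophosphamide rats 6 and 2. Shared transcription may account for part of the changes. RNA of other cells, left open above for miR-199a (1.58 and 1.84 in saline rats) and miR-143 (0.49 and 1.81), could raise both arms as well. Arms that moved apart leave room for differences in processing, stability or probe behaviour, which were not tested.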
